A study of Homo sapiens with 12 samples.

How the data were processed

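Gene expression was measured on 1-colour Illumina bead arrays with Cy3-labelled material made from total RNA of 2 established human endometrial cancer cell lines, Hec1a and Ishikawa. Each line carried either a lentiviral short hairpin RNA vector against ALCAM (shALCAM) or the empty vector (shControl). The 4 groups held 3 arrays each. The labels give each array its line, its vector and a replicate number, but they do not say whether replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The protocol names 2 hairpins against ALCAM, and the labels do not say which was carried by the cells on the arrays.

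The deposited table of intensities held 47323 probes for each of the 12 arrays, on a linear scale, without missing values. The lowest intensity of an array lay between 62.9 and 66.4 units, so no background subtraction was seen in the deposited values. Beside each intensity the deposited table gives a detection p-value, whose steps match comparison with 770 negative control beads. The authors' processed table holds log2 values of 21946 probes, which are the probes with a detection p-value under 0.01 on at least 1 array. These deposited log2 values equalled the quantile-normalized log2 intensities of those probes without background correction, with a largest difference of 5e-09, so their scale is known and no gene was centred. The median of each of the 12 columns of log2 values was 6.80. The submitters' processing notes name lumi 2.22.0. The scanner software and its settings are not given in the sources used here.

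Starting from the intensities, background correction and quantile normalization were done with neqc in limma 3.58.1 under R 4.3.3, with background statistics inferred from the detection p-values and an offset of 16, followed by log2. Probes were named through the platform annotation. Of the probes in the authors' processed table, 16604 had 1 gene symbol, 3 had several and 5339 had none. Entrez identifiers matched 16592 of them to the RefSeq gene table of GRCh38.p14, which changed 0 symbols. Probes without a symbol, and probes outside the authors' processed table, were not named and were tested apart. The 3 with several symbols were left out. A named probe was kept when its detection p-value was under 0.05 on at least 3 of the 12 arrays, which left 15897 probes of 12181 genes. For 3013 genes with more than 1 probe, the probe with the highest mean was used.

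One linear model with a coefficient per group was fitted to all 12 arrays with lmFit and eBayes, giving 8 residual and 8.45 prior degrees of freedom. The contrasts were shALCAM minus shControl in each line, the difference of these 2 effects (Ishikawa minus Hec1a), and Ishikawa shControl minus Hec1a shControl. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over the 12181 genes of 1 contrast, and a gene was called at an adjusted p under 0.05. Tests are 2-sided. Errors are the SD over 3 arrays for levels and the model's SE for log2 changes. Where a gene was not detected on any array of the dimmer group, the fold is given as a lower bound ("at least"). It was computed as the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the probe's own value and the lowest detected signal.

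Before the data were examined, 32 gene lists with 887 entries were fixed, of which 647 entries were measured. They cover ALCAM with its partners and related adhesion molecules, epithelial junctions, mesenchymal markers, integrins, basement membrane, extracellular proteolysis and the actin cytoskeleton. Further lists hold TGF-beta, YAP/TEAD, WNT, NOTCH, ERK, NF-kappaB, p53, interferon and steroid hormone responses, MHC class I presentation and NRF2 targets. They also cover the cell cycle, stem-like tumour cell markers, hypoxia with glycolysis, cholesterol and fatty acid synthesis, the unfolded protein and amino acid response, respiratory chain subunits, replication-dependent histones, metallothioneins, secretory proteins, cancer-testis antigens, and markers of leukocytes, endothelium and stroma. The 29 lists with at least 5 measured members were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists. They were tested again with the correlation estimated for each list. That second form also rests on the 8 residual degrees of freedom of the fit, which raises its p-values whatever the correlation. Metallothioneins, endothelial and stromal markers had fewer members and are only described. Some genes stand in more than 1 list.

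The genes named in the text follow a rule fixed at the same time. It takes ALCAM, the 12 largest rises and 12 largest falls in each line among called genes whose 3 shALCAM arrays all lay outside the range of the 3 shControl arrays, and up to 10 genes in each direction called in both lines the same way. It adds 6 genes called in opposite directions, the 6 largest differences of effect in each direction, and the 8 largest differences between the control lines in each direction. From each list it takes up to 4 called members, or the 2 with the lowest p where none was called. Symbols of uncharacterised loci were left out of the largest changes. A few genes that the rule selects are not reported here.

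The alternatives tried were no background correction, the authors' processed values, median scaling, no filter and a stricter filter on dim probes, all probes tested, the mean of a gene's probes, only the arrays compared, the replicate number as a block, trended and robust variance, array weights, each array left out in turn, a 2-fold minimum, a stricter threshold, and the estimated correlation for lists. The run with no filter still held only probes of the authors' processed table, 12666 genes, so it says little on dim probes. The replicate numbers did not pair the arrays. The fit was tested on simulated data with the measured means and spreads, in which 200 of 12181 genes were changed per comparison. In Hec1a it recovered 66.0% of the genes changed by 0.5 on the log2 scale and 97.0% of those changed by 1, and in Ishikawa 56.0% and 98.0%. Unchanged genes made up 3.49% of the calls in Hec1a (6 genes) and 7.06% in Ishikawa (12 genes), the latter above the 5% aimed at. A further small list was shifted to test the list method, and its members did not count as unchanged. The simulated noise was drawn independently for each gene, so variation that genes share on an array was absent. These shares may therefore not hold for the real arrays. The number of arrays limits the precision of every value. Figures were drawn with matplotlib 3.10.9.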

Results

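Expression was profiled in Hec1a and Ishikawa, 2 human endometrial cancer cell lines, after stable introduction of an shALCAM or an shControl vector. Each of the 4 combinations of line and vector was measured on 3 arrays. Between 18063 and 19365 probes, 38.2% to 40.9% of those on an array, were detected on each of the 12 arrays, and the median intensity lay between 80.9 and 84.1 units. Arrays of 1 group correlated across probes at 0.994 to 0.996, groups of the same line at 0.990 to 0.994, and arrays of different lines at 0.843 to 0.855. The first principal component held 92.9% of the variance and separated the lines. Within Hec1a the first component held 38.4% and within Ishikawa 34.0%, and in each line it separated the shALCAM from the shControl arrays.

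The first question was whether the targeted transcript was lower. ALCAM, a cell adhesion molecule of the immunoglobulin superfamily, fell in both lines. In Hec1a its log2 intensity was 8.70 ± 0.06 (SD, n = 3) with shControl and 7.51 ± 0.10 (SD, n = 3) with shALCAM, so that 43.8% of the control level was left. The log2 change was -1.19 (SE 0.0976, 95% interval -1.40 to -0.98, adjusted p = 3.56e-06). In Ishikawa the level was 8.35 ± 0.10 (SD, n = 3) with shControl and 7.32 ± 0.17 (SD, n = 3) with shALCAM, leaving 49.0%, with a log2 change of -1.03 (SE 0.0976, 95% interval -1.24 to -0.82, adjusted p = 3.01e-05). All 3 shALCAM arrays lay below all 3 shControl arrays in each line. The 2 changes differed by 0.16 (SE 0.138, adjusted p = 0.596). ALCAM was measured by 1 probe, and its fall was the 3rd largest in Hec1a and the 5th largest in Ishikawa.

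**Figure D1:**
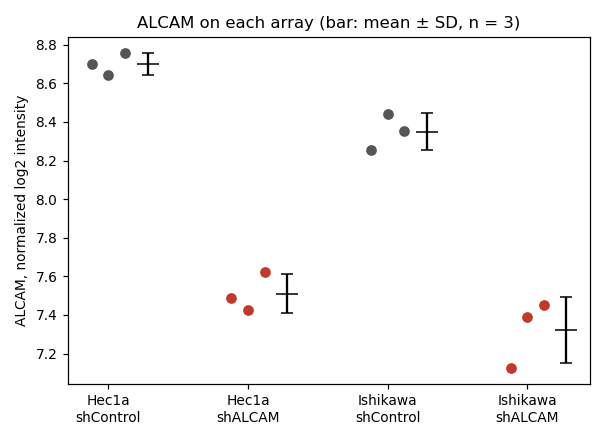
Normalized log2 intensity of the ALCAM probe (vertical axis) on each of the 12 arrays, by line and vector (horizontal axis), with grey points for shControl, red points for shALCAM and bars for the mean ± SD of 3 arrays. The shALCAM arrays lie between 7.13 and 7.62 and the shControl arrays between 8.25 and 8.76.

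In Hec1a, the comparison of shALCAM with shControl asks which transcripts differ between cells with the 2 vectors. Because the control carried the empty vector, neither line can tell effects of lower ALCAM from other effects of the hairpin. Differences between the cell pools that carried the vectors cannot be told apart from these either. PHGDH, the first enzyme of serine synthesis, fell most, from a log2 intensity of 10.43 ± 0.07 to 8.03 ± 0.12 (SD, n = 3 each), which is 5.28-fold. FGFBP1, a secreted carrier of fibroblast growth factors, fell 3.14-fold, from 9.54 ± 0.06 to 7.89 ± 0.07. CD24, a surface glycoprotein, rose most, 2.77-fold, from 7.02 ± 0.08 to 8.49 ± 0.03, followed by FHL2, a LIM-domain cofactor, which rose 2.34-fold. In all, 280 genes rose and 204 fell among the 12181 genes tested, with a median size of 0.44 on the log2 scale among them, and 12 of them changed at least 2-fold.

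Next among the falls in Hec1a was NDRG1, a gene induced by stress and low oxygen, at -1.03 on the log2 scale (SE 0.0958, adjusted p = 9.47e-06). TMOD1, which caps actin filaments, had a change of -0.99, EDAR, the ectodysplasin receptor, -0.99, and MYO7B, an unconventional myosin, -0.98. IGFBP6, which binds insulin-like growth factors, changed by -0.95, CCNA1 (cyclin A1) by -0.95, SFN (14-3-3 sigma) by -0.92, S100A14 by -0.92 and THBD (thrombomodulin) by -0.87. The adjusted p-values of these 8 genes lay between 5.69e-06 for EDAR and 0.00196 for THBD. Among the genes that rose, the adhesion or cell surface proteins TENM3, FLRT3 and CNTNAP2 changed by 1.08, 1.05 and 1.04. The actin-binding proteins SCIN and LCP1 changed by 1.01 and 0.90, and CYFIP2, a subunit of the WAVE regulatory complex, by 0.97. DACT2, an inhibitor of WNT signalling, rose at least 1.81-fold from a level at which it was not detected on any control array, and SCIN was detected on 1 of 3 control arrays. CRACDL rose by 1.04, the scaffold protein MPDZ by 0.91, and EGR1, an immediate-early transcription factor, by 0.99 (SE 0.208, adjusted p = 0.0128). The call of EGR1 ended with trended and robust variance (adjusted p = 0.0835) and without Hec1a shControl replicate 1 (adjusted p = 0.0541). The second probe of CD24 gave 0.53, less than the probe used.

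All 484 called genes had shALCAM arrays that did not overlap the shControl arrays, as did 22.9% of all genes tested, where chance gives 10%. Without Hec1a shControl replicates 1 and 2, left out in turn, 170 and 130 rose and 132 and 110 fell, and without Hec1a shALCAM replicates 1, 2 and 3 in turn 178, 158 and 157 rose and 121, 115 and 122 fell. With median scaling 152 rose and 165 fell.

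**Figure D2:**
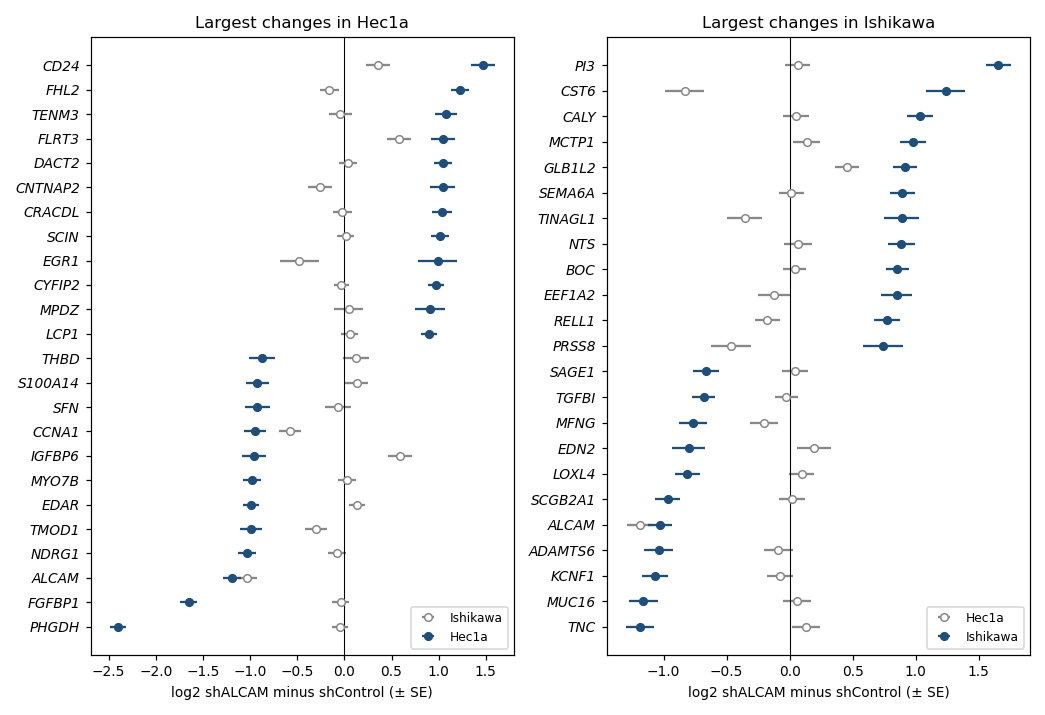
Log2 change, shALCAM minus shControl (horizontal axis, ± SE from the model over 12 arrays), of the genes with the largest rises and falls in Hec1a (left) and in Ishikawa (right), 1 gene per line of the vertical axis. Filled points give the change in the line named above the panel and open points the change of the same gene in the other line, such as -2.40 in Hec1a and -0.05 in Ishikawa for PHGDH.

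By gene list, the list of keratins and cell junction genes was called downwards in Hec1a with a preset correlation only. Of its 33 measured members, 4 fell and 0 rose, and adjusted over the list alone 5 fell and 1 rose. CLDN4 and CLDN3, tight junction claudins, fell by 0.65 and 0.46, KRT7, a simple epithelial keratin, by 0.48, and DSP, the desmosomal protein desmoplakin, by 0.36. The list's median log2 change was -0.09 (camera adjusted p = 0.00262; adjusted p = 0.189 with an estimated correlation). Of 19 genes of extracellular proteolysis, 4 fell and 0 rose, and adjusted over the list alone 4 fell and 1 rose. PLAU (urokinase) fell by 0.69 and its receptor PLAUR by 0.49, ADAM9 by 0.48, and SERPINB5 (maspin), a serpin rather than a protease, fell at least 1.07-fold to a level not detected. The list's median was -0.06 (camera adjusted p = 0.0218; adjusted p = 0.350 with an estimated correlation), and its call ended without Hec1a shALCAM replicate 3 (adjusted p = 0.0549). Of 13 markers of stem-like tumour cells, 4 rose and 0 fell, and adjusted over the list alone 4 rose and 1 fell. CD24 rose by 1.47, CD44, the hyaluronan receptor, by 0.74, and the retinaldehyde dehydrogenases ALDH1A3 and ALDH1A1 by 0.54 and 0.37. The median was 0.07 (camera adjusted p = 0.0218; adjusted p = 0.189 with an estimated correlation). That call ended without Hec1a shControl replicate 1 (adjusted p = 0.101), without Hec1a shALCAM replicate 1 (adjusted p = 0.0695) and with no filter on dim probes (adjusted p = 0.0708).

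The other lists were not called in Hec1a, with camera adjusted p-values from 0.0959 to 0.930, but many held called members in both directions. Among 32 genes of hypoxia and glycolysis, NDRG1, SLC2A1 (-0.58), ALDOC (-0.61) and ANKRD37 fell while the hexokinase HK1 (0.46) rose, and adjusted over the list alone 6 fell and 2 rose. Among 16 basement membrane genes, LAMB3 (-0.74) and LAMC1 (-0.43), chains of laminins, fell and COL4A1 (0.52) rose, with 4 falls and 1 rise adjusted over the list alone. Among 33 genes of ERK signalling, EGR1 and PHLDA1 (0.59) rose and MYC (-0.45) and EREG (-0.50) fell, with 3 rises and 6 falls adjusted over the list alone. Of 22 YAP/TEAD targets, CCN1 (0.53) and CCN2 (0.55; 0.34, adjusted p = 0.215, as the mean of its probes) rose and DLC1 (-0.58) and IGFBP3 (-0.47) fell, with 3 rises and 3 falls adjusted over the list alone. Of 41 actin genes, FSCN1 (0.51) and PALLD (0.45) rose and 2 fell, among them DIAPH1 (-0.33), with 2 rises and 3 falls adjusted over the list alone. Of 15 WNT targets, CD44 and NKD2 (0.47) rose and MYC and SOX9 (-0.36) fell, with 2 rises and 3 falls adjusted over the list alone. Of 24 NRF2 targets and antioxidant genes, TXNRD1 (-0.57), EPHX1 (-0.40) and SRXN1 (-0.35) fell and 0 rose, with 4 falls adjusted over the list alone.

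In the unfolded protein and amino acid response list of 34 genes, DDIT3 (0.70) rose and PHGDH fell, and the counts adjusted over the list alone were the same. In the list of 18 genes that holds ALCAM, its partners and related adhesion molecules, ALCAM fell and CEACAM1 rose at least 1.30-fold. Adjusted over the list alone, 3 fell and 3 rose. Of 23 steroid hormone genes, CA12 (0.38) and STC2 (0.41) rose and MUC1 (-0.35) fell, with 2 rises and 2 falls adjusted over the list alone. Of 16 NOTCH genes LFNG (0.31) rose and HES4 (-0.48) fell, and of 15 mesenchymal genes COL6A1 (0.42) rose and S100A4 (-0.37) fell, each with 1 rise and 1 fall adjusted over the list alone. A single gene was called in several lists. ITGB4 (-0.62) fell among 19 integrins, TGFBR3 (-0.42) among 24 TGF-beta genes, ACAT2 (-0.46) among 20 cholesterol synthesis genes and MUC1 among 11 mucins and secretory proteins. Adjusted over the list alone, 1 fell among the integrins, 1 fell and 1 rose among the TGF-beta genes, 1 fell in cholesterol synthesis, and 3 fell and 1 rose among the secretory proteins. ACACB (0.48) rose among 14 fatty acid genes, H4C14 (0.67) among 9 histones, HERC5 (0.51) among 30 interferon genes, PSMB9 (0.41; 0.19, adjusted p = 0.227, as the mean of its probes) among 15 MHC class I genes and MT1X (0.42) among 4 metallothioneins. Adjusted over the list alone these lists held 3 rises, 2 rises, 2 rises, 1 rise with 2 falls, and 1 rise. None of 47 cell cycle genes, 38 respiratory chain subunits, 23 p53 targets, 9 cancer-testis antigens, 8 leukocyte, 2 endothelial or 4 stromal markers was called, also adjusted over the list alone. Of 16 NF-kappaB genes 0 were called, and adjusted over the list alone 3 rose and 2 fell. Of the list members named, LFNG lost its call under 7 of 11 other settings (adjusted p up to 0.280), IGFBP3 under 6 (up to 0.141), MUC1 under 5, CLDN4, CA12, STC2, S100A4 and DIAPH1 under 4 each (up to 0.153), and SRXN1, DSP and SOX9 under 3 each (up to 0.0997). With single arrays left out, LFNG, CLDN4, S100A4, DIAPH1 and SRXN1 lost their calls without each of the 6 Hec1a arrays, IGFBP3, MUC1, STC2, DSP, ADAM9, NKD2 and TGFBR3 without 5, CA12, SOX9, ALDH1A1, DLC1 and SERPINB5 without 4, and EPHX1, EREG and PALLD without 3 (adjusted p up to 0.194). Without background correction the values of CLDN4 (-0.24), CEACAM1 (0.16), HERC5 (0.17), IGFBP3 (-0.19) and LFNG (0.10) were much smaller and not called. ANKRD37 and MT1X were not followed through the alternatives. The cell cycle genes with the lowest p, TYMS and CCNE1, had log2 changes of -0.29 (adjusted p = 0.131) and -0.26 (adjusted p = 0.162). Median and mean differed in sign for cholesterol synthesis, cancer-testis antigens and the unfolded protein response.

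In Ishikawa the same comparison gave a different set of leading genes. PI3, the protease inhibitor elafin, rose most, 3.15-fold, from a log2 intensity of 4.64 ± 0.12 to 6.30 ± 0.18 (SD, n = 3 each). CST6, the cysteine protease inhibitor cystatin E/M, rose 2.36-fold, from 7.90 ± 0.27 to 9.14 ± 0.38. TNC, the matrix glycoprotein tenascin C, fell 2.28-fold, from 9.75 ± 0.14 to 8.56 ± 0.08, and MUC16, the cell surface mucin that carries the CA125 antigen, fell 2.24-fold, from 7.04 ± 0.12 to 5.88 ± 0.06. In all, 103 genes rose and 63 fell among the 12181 tested, with a median size of 0.52 on the log2 scale among them, and 9 changed at least 2-fold.

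Other genes with large rises in Ishikawa were CALY (1.04), MCTP1 (0.98), GLB1L2 (0.92), the semaphorin SEMA6A (0.90), TINAGL1 (0.89), the neuropeptide precursor NTS (0.89) and BOC, a Hedgehog co-receptor (0.86). EEF1A2, a translation elongation factor, rose by 0.85, RELL1 by 0.77, and PRSS8, the membrane serine protease prostasin, by 0.74 (SE 0.159, adjusted p = 0.0263), a call lost under 2 of 11 other settings and without 5 of the 6 Ishikawa arrays (adjusted p up to 0.116). The second probes of CALY (0.11) and RELL1 (0.02) did not follow the probes used, the call of RELL1 ended with the mean of its probes (0.40, adjusted p = 0.0721), and the second probe of TNC gave less (-0.66). Among the falls were the potassium channel subunit KCNF1 (-1.07), the metalloprotease ADAMTS6 (-1.04) and SCGB2A1, a secretoglobin (-0.97). LOXL4, a lysyl oxidase of the matrix, changed by -0.81, EDN2 (endothelin 2) by -0.80, MFNG, a glycosyltransferase that modifies NOTCH receptors, by -0.76, the matrix protein TGFBI by -0.68 and the cancer-testis antigen SAGE1 by -0.66. The adjusted p-values of these 8 falls lay between 3.01e-05 for KCNF1 and 0.00453 for EDN2.

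All 166 called genes had arrays that did not overlap between the vectors, as did 18.2% of all genes tested. Without Ishikawa shControl replicates 1, 2 and 3, left out in turn, 73, 65 and 34 rose and 37, 39 and 27 fell, and without Ishikawa shALCAM replicates 2 and 3 in turn 56 and 48 rose and 38 and 37 fell. With median scaling 128 rose and 37 fell, and without background correction 199 rose and 125 fell.

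Both lists of lipid synthesis genes were called upwards in Ishikawa with a preset correlation only, and no member passed the test over all genes. Of 14 fatty acid synthesis genes 0 were called, and adjusted over the list alone 5 rose and 0 fell. The desaturases FADS1 and SCD had log2 values of 0.33 (adjusted p = 0.0510) and 0.35 (adjusted p = 0.0664), and the list's median was 0.17 (camera adjusted p = 0.00356; adjusted p = 0.129 with an estimated correlation). Of 20 cholesterol synthesis genes 0 were called, and adjusted over the list alone 3 rose and 0 fell. MSMO1 and IDI1 had values of 0.40 (adjusted p = 0.0756) and 0.30 (adjusted p = 0.135), and the median was 0.11 (camera adjusted p = 0.0133; adjusted p = 0.185 with an estimated correlation). The cholesterol call ended without Ishikawa shControl replicate 3 (adjusted p = 0.0550). Of 23 steroid hormone genes 4 fell and 1 rose, and adjusted over the list alone 6 fell and 1 rose. SCGB2A1 fell by 0.97, GREB1, a gene induced by oestrogen, by 0.57, the secretoglobin SCGB1D2 by 0.52 and SPP1 (osteopontin) by 0.45, while PTGES, a prostaglandin E synthase, rose at least 1.29-fold from a level not detected. PTGES lost its call under 4 of 11 other settings (adjusted p up to 0.122) and without 3 of the 6 Ishikawa arrays, and SCGB1D2 under 2 settings and without 4 arrays (up to 0.0872), while SPP1 was not followed through the alternatives. The median was -0.13 (camera adjusted p = 0.00356; adjusted p = 0.133 with an estimated correlation).

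Of 15 MHC class I genes HLA-F rose by 0.36 (adjusted p = 0.0473) and 0 fell, with 2 rises adjusted over the list alone. The call of HLA-F ended under 9 of 11 other settings (adjusted p up to 0.314) and without each of the 6 Ishikawa arrays (up to 0.180). Its value was 0.18 without background correction and 0.24 as the mean of its probes. The list's median was 0.14 (camera adjusted p = 0.0234; adjusted p = 0.133 with an estimated correlation). The list's call ended with median scaling (adjusted p = 0.0623), without Ishikawa shControl replicate 3 (adjusted p = 0.0821) and without Ishikawa shALCAM replicate 2 (adjusted p = 0.0625). Of 19 proteolysis genes 0 were called, also adjusted over the list alone, with values of 0.34 for ADAM19 and 0.30 for TIMP2, an inhibitor of metalloproteinases. The median was 0.13 (camera adjusted p = 0.0330; adjusted p = 0.306 with an estimated correlation). The call ended without Ishikawa shControl replicate 3 (adjusted p = 0.324) and without Ishikawa shALCAM replicate 1 (adjusted p = 0.129), and under 3 other choices of probes adjusted p lay between 0.0518 and 0.0764.

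The remaining lists were not called in Ishikawa, with camera adjusted p-values from 0.0736 to 0.925. Of 11 secretory proteins SLPI (0.63), a leukocyte protease inhibitor, and WFDC2 (0.51) rose while MUC16 and SCGB2A1 fell, with 3 rises and 2 falls adjusted over the list alone. Of 30 interferon genes IFI6 (0.57) and IFITM1 (0.60) rose and IFI35 (-0.46) fell, with 3 rises and 1 fall adjusted over the list alone. Of 16 NOTCH genes the ligands DLL3 (0.50; 0.32, adjusted p = 0.118, as the mean of its probes) and JAG1 (0.42) rose, with 3 rises and 1 fall adjusted over the list alone. Of 15 mesenchymal genes CDH2 (N-cadherin, 0.62) rose and TNC fell, with 1 rise and 4 falls adjusted over the list alone. Of 24 TGF-beta genes ID3 (0.59) rose and TGFBI fell, with 2 rises and 4 falls adjusted over the list alone. Of 13 stem-like cell markers PROM1 (0.44) rose and ALDH1A3 (-0.59) fell, also adjusted over the list alone. Single called members were ACTA2 (0.57) among actin genes, the chemokine CXCL1 (0.65), the death receptor FAS (0.50), SOX9 (0.46), CRIM1 (0.55), JUN (-0.52) and SLC2A1 (-0.38). Of the members named in this paragraph, SLC2A1 and JUN lost their calls under 4 of 11 other settings each (adjusted p up to 0.247 and 0.0927) and CRIM1 and IFI35 under 3 each (up to 0.0891 and 0.132). With single arrays left out, SLC2A1, JUN, CRIM1, ID3 and WFDC2 lost theirs without 5 of the 6 Ishikawa arrays, ACTA2, CXCL1, FAS, IFI35, IFITM1, JAG1 and SLPI without 4, and PROM1 and SOX9 without 3 (adjusted p up to 0.173). Without background correction the values of CXCL1 (0.22) and IFI35 (-0.15) were much smaller and not called. Adjusted over the list alone, 1 actin gene, 2 p53 targets, 1 WNT target and 1 YAP/TEAD target rose, 2 NF-kappaB genes rose and 1 fell, 5 ERK genes fell and 1 hypoxia gene fell. ALCAM was the called member in the list of its partners and related molecules, with 2 rises and 2 falls adjusted over the list alone. Of 47 cell cycle genes 0 were called, also adjusted over the list alone. Of 38 respiratory chain subunits 0 were called, and adjusted over the list alone 4 rose. In the other lists 0 were called, and adjusted over the list alone 1 keratin or junction gene and 1 gene of the unfolded protein response rose, 1 integrin rose and 1 fell, and 1 basement membrane gene, 1 cancer-testis antigen and 2 of 4 stromal markers fell. NRF2 targets, histones, metallothioneins, leukocyte and endothelial markers held 0 called genes either way. Median and mean differed in sign for leukocyte markers, mesenchymal genes, secretory proteins and the unfolded protein response.

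**Figure D3:**
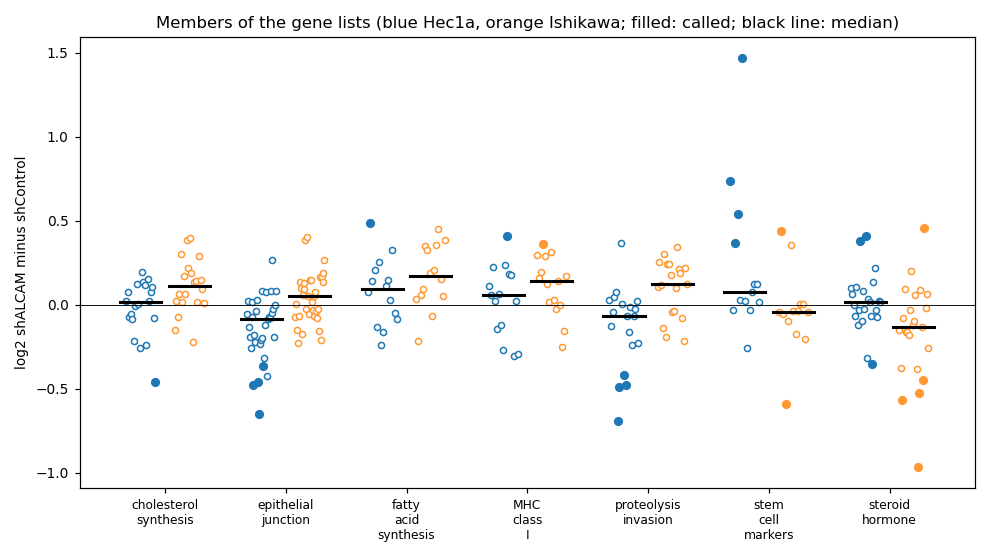
Log2 change, shALCAM minus shControl (vertical axis), of each measured member of the gene lists called in at least 1 line (horizontal axis), in Hec1a (blue) and Ishikawa (orange), with filled points for genes called over all genes and black lines for the median. The medians of the keratin and junction list are -0.09 in Hec1a and 0.05 in Ishikawa, and those of fatty acid synthesis 0.09 and 0.17.

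Comparison of the lines asks whether the shALCAM vector went with the same changes in both. ALCAM itself, CCNA1, the glucose transporter SLC2A1 and PADI3, a protein arginine deiminase, fell in both lines, and FLRT3, GLB1L2 and ACAT1, a mitochondrial thiolase, rose in both. These 7 genes compare with 3.42 expected from lists of these sizes drawn independently. With ALCAM left out, because it was targeted in both lines, 3 shared falls stood against 1.03 expected (hypergeometric adjusted p = 0.169 over 4 overlaps) and 3 shared rises against 2.37 (adjusted p = 0.564), a test chosen after the overlap had been seen. Apart from ALCAM, each shared gene lost a call under some alternatives, with adjusted p up to 0.247 for SLC2A1, 0.169 for PADI3, 0.134 for FLRT3 and 0.0967 for CCNA1 in Ishikawa, 0.0592 for GLB1L2 in Hec1a, and 0.183 and 0.163 for ACAT1 in Hec1a and Ishikawa. In opposite directions, 7 genes fell in Hec1a and rose in Ishikawa, against 1.72 expected (adjusted p = 0.00662). They included CST6 (-0.83 and 1.24), IGFBP6 (-0.95 and 0.59), the mucin-like protein FCGBP (-0.41 and 0.60), MSLN, the surface antigen mesothelin (-0.59 and 0.45), EMP3 (-0.41 and 0.50) and SOX9 (-0.36 and 0.46). ALDH1A3 rose in Hec1a (0.54) and fell in Ishikawa (-0.59), the only gene of that kind against 1.43 expected (adjusted p = 0.764). The lines shared the same estimate of spread for each gene, so genes of small spread are more readily called in both. The expected counts assume lists drawn independently, so they tend to be too low and the hypergeometric p-values too small. CST6 and ALDH1A3 kept both calls under 11 other settings and without any single array, though neither reached 2-fold in Hec1a and the second probe of ALDH1A3 gave less (0.31 and -0.23), while adjusted p reached 0.145 for FCGBP, 0.118 for SOX9 and 0.0872 for EMP3 in Hec1a, and 0.147 for IGFBP6 and 0.103 for MSLN in Ishikawa.

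Across the 12181 genes, the log2 changes of the lines correlated at 0.0016 (Pearson) and -0.0029 (Spearman), and at -0.03 over the 635 genes called in either line without ALCAM. These correlations and overlaps run across genes, which are not independent replicates. The overlaps moved with the processing, from 21 genes in the same direction with trended and robust variance to 1 with a 2-fold minimum, and from 17 in opposite directions without background correction to 0 with a 2-fold minimum. Without Ishikawa shControl replicate 3 there were 2 and 3. Left out in turn, Ishikawa shALCAM replicates 2 and 3 gave 4 and 3 in the same and 5 and 5 in opposite directions, Ishikawa shControl replicate 1 gave 4 in the same and replicate 2 gave 5 in opposite directions.

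**Figure D4:**
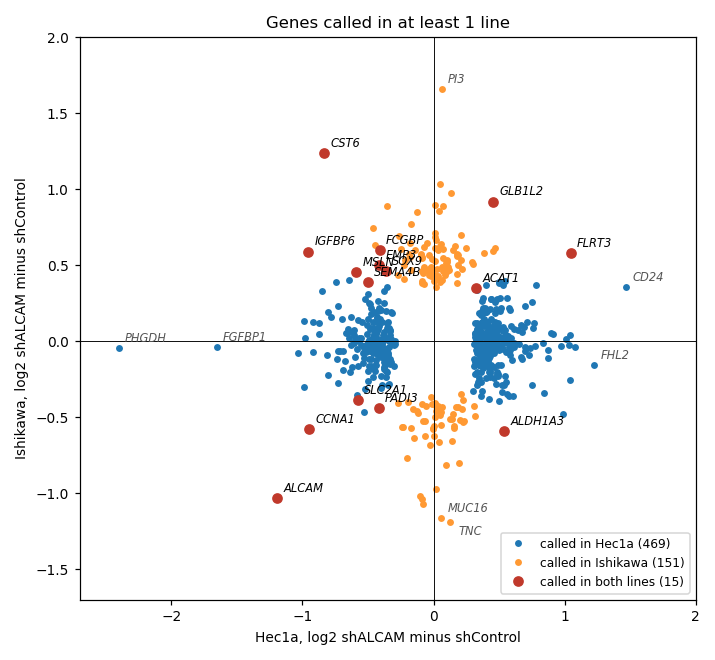
Log2 change, shALCAM minus shControl, in Hec1a (horizontal axis) and Ishikawa (vertical axis) of the genes called in at least 1 line, with blue for Hec1a alone, orange for Ishikawa alone and red for both. The 15 red genes hold 7 with the same and 8 with opposite directions, and most other points lie near an axis, with r = -0.03 over all points without ALCAM.

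The effect of shALCAM differed between the lines for 270 genes by the test of the difference itself, with 128 more positive and 142 more negative in Ishikawa. The largest differences of the log2 changes, Ishikawa minus Hec1a, were 2.35 for PHGDH (adjusted p = 1.11e-08) and 2.07 for CST6 (adjusted p = 0.000119). FGFBP1 (1.61), PI3 (1.59), IGFBP6 (1.54) and TINAGL1 (1.25) followed. In the other direction stood EGR1 (-1.47, adjusted p = 0.0122), FHL2 (-1.39), TNC (-1.32), CNTNAP2 (-1.30), MUC16 (-1.22) and VCAN, the proteoglycan versican (-1.18). The difference of EGR1 lost its call with trended and robust variance (adjusted p = 0.0879). PHGDH had a log2 value of -0.05 (adjusted p = 0.875) in Ishikawa, and PI3 was not detected on any Hec1a array. CD24 differed by -1.12 (adjusted p = 0.00246), with 1.47 in Hec1a and 0.35 in Ishikawa. Its second probe differed less, with 0.53 and 0.21. Without Ishikawa shControl replicate 3 the count was 177, without Ishikawa shALCAM replicate 2 it was 178, and without background correction it was 504.

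The lists called in the difference, with a preset correlation only, were proteolysis, keratins and junctions, stem-like cell markers, hypoxia with glycolysis, and cholesterol and steroid hormone genes. For proteolysis the median difference was 0.22 (camera adjusted p = 0.000883; adjusted p = 0.134 with an estimated correlation), with PLAUR (0.73) called, and adjusted over the list alone 5 more positive genes. For keratins and junctions it was 0.19 (camera adjusted p = 0.00145; adjusted p = 0.134 with an estimated correlation), with CLDN4 (1.05) called, and 2 more positive and 1 more negative gene adjusted over the list alone. The call of CLDN4 ended with the replicate block (adjusted p = 0.0785) and without 5 of the 12 arrays (up to 0.0563). For stem-like cell markers it was -0.12 (camera adjusted p = 0.0291; adjusted p = 0.134 with an estimated correlation), with ALDH1A3 (-1.13), CD24, CD44 (-0.78) and PROM1 (0.47) called. Adjusted over the list alone, 1 of these markers was more positive and 4 were more negative. The call of PROM1, which was not detected in Hec1a, ended under 4 of 11 other settings (adjusted p up to 0.119) and without each of the 12 arrays (up to 0.104). For hypoxia and glycolysis it was 0.10 (camera adjusted p = 0.0291; adjusted p = 0.324 with an estimated correlation), with NDRG1 (0.96) and ALDOC (0.67) called, and 2 more positive and 1 more negative adjusted over the list alone. For cholesterol synthesis it was 0.15 (camera adjusted p = 0.0322; adjusted p = 0.283 with an estimated correlation) with 0 members called and 2 more positive adjusted over the list alone. For steroid hormone genes it was -0.13 (camera adjusted p = 0.0349; adjusted p = 0.283 with an estimated correlation), with SCGB2A1 (-0.99), SPP1 (-0.67) and CA12 (-0.56) called, and 3 more positive and 8 more negative adjusted over the list alone. The call of CA12 ended under 4 of 11 other settings (adjusted p up to 0.101) and without 8 of the 12 arrays (up to 0.0904), and that of SPP1 with median scaling (0.0620). The calls of the last 4 of these lists ended without Hec1a shControl replicate 1, with adjusted p-values of 0.0907, 0.126, 0.0907 and 0.0907. Each also ended without other single arrays, at 0.0506 without Hec1a shALCAM replicate 1 for the stem-like, cholesterol and steroid lists, and for the last 3 at up to 0.0624, 0.0880 and 0.126 without Ishikawa shALCAM replicate 1, Hec1a shALCAM replicate 2 and Ishikawa shALCAM replicate 2.

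Among members of the other lists, the differences were also called for the secretory proteins SLPI (1.08), LCN2 (0.87) and MUC16, the YAP/TEAD targets CCN1 (-0.82) and CCN2 (-0.82), the basement membrane genes LAMB3 (0.62), LAMC1 (0.56) and COL4A1 (-0.67), the TGF-beta genes TGFBR3 (0.62) and TGFBI (-0.66, not detected in Hec1a), COL6A1 (-0.53), ACTA2 (0.76), CXCL1 (0.83), FAS (0.72), SOX9 (0.82), JUN (-0.75), MYC (0.54), TXNRD1 (0.60), TAPBP (0.58) and DDIT3 (-0.74). The same held for ACACB (-0.70), the histone H4C14 (-0.78, not detected in Ishikawa), the cancer-testis antigen CT45A5 (-0.81), the respiratory chain subunit NDUFB9 (0.69) and the integrin ITGA10 (-0.50, not detected in Hec1a). Of these, ITGA10 lost its call under 6 of 11 other settings (adjusted p up to 0.127), COL6A1 under 3 (up to 0.126), MYC, LAMB3, LAMC1, TGFBR3 and NDUFB9 under 2 each (up to 0.101) and JUN under 1 (0.0730). With single arrays left out, MYC and ITGA10 lost theirs without 10 of the 12 arrays, LAMB3 and TGFBR3 without 9, COL6A1 and NDUFB9 without 8, LAMC1 without 7 and JUN without 6 (adjusted p up to 0.0988). The calls of TAPBP, ACTA2, CXCL1, CT45A5, DDIT3 and TXNRD1 ended in fewer of these runs, with adjusted p up to 0.0753. Camera adjusted p-values of the other lists lay between 0.231 and 0.923. Median and mean differed in sign for the basement membrane and NF-kappaB lists.

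The control cells show how far the lines differ without shALCAM. TGFBI and THBS1 (thrombospondin 1), matrix proteins induced by TGF-beta, were at least 176-fold and at least 160-fold higher in Ishikawa shControl than in Hec1a shControl, where neither was detected. KIF1A, a kinesin motor, was at least 130-fold higher, PROM1 (prominin 1) at least 126-fold, FBN2 (fibrillin 2) at least 121-fold, MAGED1 at least 106-fold, SPON1 136-fold and COL9A2 at least 56.1-fold. Lower in Ishikawa were TM4SF4 (at least 80.2-fold), TM4SF1 (79.0-fold), the peptide transporter TAP1 (at least 61.2-fold), IER3 (60.9-fold), MAG (at least 51.3-fold), ALDH1A1 (53.5-fold), LGALS3BP (43.6-fold) and the kallikrein KLK11 (at least 37.6-fold). In all, 8589 of the 12181 genes differed, 4211 higher and 4378 lower in Ishikawa, and 2616 of them differed at least 2-fold. ALCAM was 1.28-fold lower in Ishikawa (adjusted p = 0.00400).

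NOTCH genes stood higher in Ishikawa, 13 of 16 (median 1.48, camera adjusted p = 0.000408; adjusted p = 0.10 with an estimated correlation), with HES2 at least 35.8-fold and JAG1 at least 10.5-fold higher and NOTCH3 at 3.80 on the log2 scale. Of 23 steroid hormone genes 16 were higher and 5 lower (median 1.40, camera adjusted p = 0.00236; adjusted p = 0.10 with an estimated correlation), led by MSX1 (4.78) and SCGB2A1 (at least 19.6-fold). Of 15 mesenchymal genes 11 were higher and 4 lower (median 3.15, camera adjusted p = 0.00795; adjusted p = 0.103 with an estimated correlation), among them TNC (5.21), CDH2 (at least 13.1-fold), COL1A2 (at least 13.8-fold) and, lower, S100A4 (-4.61). Cholesterol synthesis had 13 of 20 higher (median 0.84, camera adjusted p = 0.0219; adjusted p = 0.103 with an estimated correlation). Stem-like cell markers had 8 of 13 higher (median 0.60, camera adjusted p = 0.0311; adjusted p = 0.103 with an estimated correlation). Interferon genes were lower in Ishikawa, 24 of 30 (median -0.96, camera adjusted p = 0.000777; adjusted p = 0.10 with an estimated correlation), including OAS3 (at least 9.45-fold) and IFIH1 (at least 4.77-fold). MHC class I genes were lower for 9 and higher for 4 of 15 (median -0.83, camera adjusted p = 0.0397; adjusted p = 0.103 with an estimated correlation), including PSMB8 (at least 14-fold), PSMB9 (at least 12.6-fold) and TAP2 (at least 10.5-fold) beside TAP1.

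Cell cycle genes were lower for 31 of 47 (median -0.41, camera adjusted p = 0.00507; adjusted p = 0.10 with an estimated correlation), among them BIRC5 (-1.71) and TK1 (-1.66). NRF2 and antioxidant genes were lower for 16 of 24 (median -0.76, camera adjusted p = 0.010; adjusted p = 0.10 with an estimated correlation), among them the aldo-keto reductases AKR1C3 (-5.23) and AKR1C2 (-4.22), while TXNIP was at least 22.4-fold higher. ERK genes were lower for 18 of 33 (median -0.35, camera adjusted p = 0.0219; adjusted p = 0.103 with an estimated correlation), with IER3 at -5.93 and DUSP5 at -4.39. Respiratory chain subunits were lower for 23 of 38 (median -0.31, camera adjusted p = 0.0240; adjusted p = 0.103 with an estimated correlation), although UQCRH was at least 17.1-fold higher. NF-kappaB genes were lower for 10 of 16 (median -0.59, camera adjusted p = 0.0450; adjusted p = 0.103 with an estimated correlation), a call that ended without Hec1a shControl replicate 1 (adjusted p = 0.0622) and without background correction (adjusted p = 0.0609). The call of MHC class I ended with the authors' processed values (adjusted p = 0.0507), and that of stem-like cell markers with the mean of a gene's probes (adjusted p = 0.0760). In all of these lists the counts adjusted over the list alone were the same. Called the other way, 7 cell cycle, 5 NRF2, 7 ERK, 3 respiratory chain, 2 NF-kappaB and 5 interferon genes were higher in Ishikawa. Likewise 2 NOTCH genes, 4 cholesterol synthesis genes and 1 stem-like cell marker were lower. The other lists were not called between the control lines, with camera adjusted p-values from 0.0637 to 0.972. The leukocyte list tested slightly downwards (adjusted p = 0.972) with a median of 0.02 and a mean above 0.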

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

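The tests on ATF4 target genes, on detection of the Ishikawa calls in Hec1a, on splits of the arrays for gene lists and on regroupings for gene lists and for genes called in opposite directions were chosen after the results they concern had been seen.

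Most genes called with shALCAM in 1 line were not called in the other, and 15 of 635 were called in both. The test of the difference called 270 genes. Of 200 possible regroupings of the arrays within the lines, 100 were drawn. Of these 1, the real one, called as many, with 99 genes as the highest of the others. The regrouping that swaps the vectors in Ishikawa alone was not drawn. All others drawn mix the vectors within groups of at least 1 line, which can raise the spread and lower their counts. The share of regroupings therefore does not decide whether the difference arose by chance. The largest differences of the log2 changes, Ishikawa minus Hec1a, were 2.35 for PHGDH, 2.07 for CST6, 1.61 for FGFBP1, 1.59 for PI3, 1.54 for IGFBP6 and 1.25 for TINAGL1, and -1.47 for EGR1 (a call lost with trended and robust variance), -1.39 for FHL2, -1.32 for TNC, -1.30 for CNTNAP2, -1.22 for MUC16 and -1.18 for VCAN. Genes that moved in opposite directions differed by 1.04 (MSLN), 1.01 (FCGBP), 0.92 (EMP3) and -1.13 (ALDH1A3). The lists called in the difference between the lines, with a preset correlation only, had adjusted p-values of 0.000883 for proteolysis, 0.00145 for keratins and junctions, 0.0291 for stem-like cell markers, 0.0291 for hypoxia and glycolysis, 0.0322 for cholesterol synthesis and 0.0349 for steroid hormone genes. With an estimated correlation these were 0.134 for the first 3, 0.324 for hypoxia and glycolysis and 0.283 for the last 2, so that 0 lists were called. With the preset correlation, of 100 regroupings 1, the real one, called as many as these 6 lists, and the highest of the others called 5. The limits given for the gene counts hold for this share too.

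Regroupings do not test the overlaps. Of 100, 1, the real one, gave 7 genes in the same direction and 1 gave 8 in opposite directions, but the others gave 0 because other splits of a line called 0 genes to share. Chance therefore stays open for both overlaps. The hypergeometric test of the opposite directions assumed lists drawn independently, so it does not settle this. For the counts within a line the 10 splits of 6 arrays are too few for a share under 0.05. The real splits gave 484 genes in Hec1a, 166 in Ishikawa and 8589 between the control lines, with 0 as the highest of the others, so that 1 split of 10 reached each count. For lists, with the preset correlation, the real splits gave 3 in Hec1a, 5 in Ishikawa and 12 between the control lines, and the highest of the others gave 1, 1 and 6, so that again 1 split of 10 reached each count.

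If power were lacking in Ishikawa, the genes called in Hec1a would move there by similar amounts, but over 382 such genes the slope of the Ishikawa on the Hec1a change was -0.0083 (bootstrap 95% interval -0.0532 to 0.0334), and in the other direction over 89 genes it was -0.0597 (-0.187 to 0.0736). Of the genes called in Hec1a, 79.1% were detected on all 6 Ishikawa arrays, which argues against absent expression as the reason for most of them. Of those called in Ishikawa, 54.2% were detected on all 6 Hec1a arrays, so absent expression in Hec1a stays open for the others, PI3 among them. A mixture of the lines is not borne out either, since the median change of the 50 genes most specific to the other line was 0.0155 in Hec1a (-0.0051 to 0.0400) and 0.0173 in Ishikawa (-0.0076 to 0.0466). A difference between the lines themselves, or between the hairpins or cell pools used in each, stays open and was not tested, because the labels do not say which hairpin was used.

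In Hec1a, PHGDH fell by 2.40 on the log2 scale, more than ALCAM itself, and did not move in Ishikawa beyond its error. The 20 nearest measured genes, 10 on each side in GRCh38.p14, had a median change of 0.0357 (bootstrap 95% interval 0.0016 to 0.128). Loss of a chromosome segment that spans most of them is therefore not borne out. Their median cannot show a loss limited to PHGDH and a few neighbours. The nearest measured genes on either side, ZNF697 (0.0031, adjusted p = 0.993) and NOTCH2 (0.0882, adjusted p = 0.744), did not fall. WARS2, next beyond ZNF697, rose (0.39, adjusted p = 0.0363). A loss that stops short of these genes stays open. A general fall of the ATF4 amino acid programme is not borne out either, because 10 other targets, among them PSAT1 and ASNS, had a median change of 0.0533 (-0.0372 to 0.219). A direct effect of the hairpin on another transcript, or a property of the cells that grew out with the vector, stays open, and either could be a candidate source that these arrays cannot test.

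Among probes not named here, which no comparison above used, 20 of 6171 were called in Hec1a and 13 in Ishikawa. They include probes outside the authors' processed table, whose gene symbols were not available here.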

How the results depend on the processing

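ALCAM fell under every alternative run, from -0.97 to -1.25 in Hec1a and from -0.80 to -1.09 in Ishikawa, single arrays left out included. Of the values of named called genes under other settings, 3033 of 3220 stayed past the threshold and 187 did not, and with single arrays left out 1762 of 2106 stayed and 344 did not, while 0 turned. These values include genes named for the control lines, where differences were much larger. Of all genes called in Hec1a, other settings kept 52.9% (only the groups compared) to 98.8% (array weights). Single arrays left out kept 46.3% to 62.6% of them. In Ishikawa the shares were 45.2% (replicate block) to 98.8% (stricter filter) and 34.9% to 63.3%. The cause of the changed counts was not tested, except that stricter thresholds leave fewer calls by construction. Leaving out an array can also add calls. Without Ishikawa shALCAM replicate 1, 153 genes were called in Ishikawa, of which 105 were among the 166 of the main run. The counts below are genes higher and lower in Hec1a (280 and 204), higher and lower in Ishikawa (103 and 63), shared in the same and in opposite directions (7 and 8), and differing between the lines (270), where they moved by over 1.5 times. Without background correction they were 199 and 125 in Ishikawa, 20, 17 and 504. The authors' processed values gave 201 and 125 in Ishikawa, 20, 17 and 502. Median scaling gave 152 higher in Hec1a and 37 lower in Ishikawa. Trended and robust variance gave 160 and 99 in Ishikawa, 21, 16 and 415. All probes tested gave 180 higher in Hec1a, 4 opposite and 172. Only the groups compared gave 146 and 115, 62 and 38, 3 and 3. An adjusted p under 0.01 gave 81 and 69, 33 and 23, 1, 2 and 107. A 2-fold minimum gave 8 and 4, 3 and 6, 1, 0 and 29, and 2616 between the control lines. The replicate block gave 151 and 111, 44 and 31, 4, 2 and 146. The replicate numbers did not pair the arrays, since deviations of same-numbered arrays correlated at -0.16 to -0.03 and 0 arrays matched best with their own number. With single arrays left out the ranges were 130 to 229 and 110 to 141 in Hec1a, 34 to 93 and 27 to 60 in Ishikawa, 2 to 8 and 3 to 8 shared, 177 to 258 differing, and 8144 to 8255 between the control lines. The lowest counts in Ishikawa came without Ishikawa shControl replicate 3, and those in Hec1a without Hec1a shControl replicate 2. For lists, the run with an estimated correlation changed the degrees of freedom too, so its losses do not measure correlation alone. Of the lists called in Hec1a or Ishikawa, fatty acid synthesis (-0.0445), MHC class I (-0.0163) and stem-like markers (-0.0138) had estimates below the preset 0.01. Estimates for junctions, proteolysis, cholesterol and steroid hormone genes lay above it. With that run every list call ended. Adjusted p was then 0.189 for junctions, 0.189 for stem-like markers and 0.350 for proteolysis in Hec1a, 0.129 for fatty acid, 0.185 for cholesterol, 0.133 for steroid hormone and MHC class I genes and 0.306 for proteolysis in Ishikawa. It was 0.134 for proteolysis, junctions and stem-like markers, 0.324 for hypoxia and 0.283 for cholesterol and steroid hormone genes in the difference between lines, and 0.10 or 0.103 for the 12 lists between the control lines. Other settings ended calls of stem-like markers in Hec1a (no filter 0.0708), of MHC class I (median scaling 0.0623) and proteolysis in Ishikawa (strict filter 0.0518, mean of probes 0.0764, no filter 0.0693). Between the control lines they ended those of MHC class I (authors' values 0.0507), stem-like markers (mean of probes 0.0760, no filter 0.0543) and NF-kappaB (strict filter 0.0582, median scaling 0.0536, no background correction or authors' values 0.0609, no filter 0.0706). With single arrays left out adjusted p ranged, in Hec1a, from 0.0203 to 0.0549 for proteolysis, 0.0109 to 0.101 for stem-like markers and 0.000346 to 0.0225 for junctions. In Ishikawa it ranged from 0.00506 to 0.0550 for cholesterol, 0.0132 to 0.0821 for MHC class I and 0.0102 to 0.324 for proteolysis. In the difference it ranged from 0.0139 to 0.0907 for cholesterol, 0.0121 to 0.126 for hypoxia, 0.0129 to 0.0907 for stem-like markers and 0.0104 to 0.126 for steroid hormone genes, and for NF-kappaB between the control lines from 0.0391 to 0.0622. A block by slide was not run, because the files give no slide. Signal over background limits the changes of genes near the lowest detected log2 signal, which lay between 4.48 and 4.53.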

Other observations

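The search for runs of neighbouring genes and the tests of genes 50 apart and of differences between arrays of 1 group were chosen after the results they concern had been seen, while the test of adjacent genes was planned before. In Hec1a, 11 measured genes in a row from SPRR1A to S100A1, a run of small proline-rich and S100 genes in which S100A14 (-0.92), S100A6 (-0.44) and S100A4 (-0.37) fell, had a median log2 change of -0.32 with shALCAM. Another 11 from SAMD11 to B3GALT6 had a median of -0.30, and 11 from OR8G2P to TMEM218 a median of 0.280. The largest such median reached 0.279 in size at the 95th percentile of shuffled gene orders. In Ishikawa, 11 genes from KCTD13 to MAPK3 had a median of -0.29 and 11 from CT45A1 to SOX3 a median of -0.28, against 0.247 in shuffled orders. The shuffled orders were searched at fewer starting genes than the real order, so both bounds lie too low. They do not show that a run exceeds chance, least of all the run of 0.280 beside its bound of 0.279. The gene order is that of GRCh38.p14.

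Differences in copy number between the shALCAM and shControl cells are a hypothesis that could account for such runs. The log2 changes of adjacent genes correlated at 0.0688 in Hec1a and 0.0554 in Ishikawa, above all shuffled orders (p = 0.000999 each, the smallest they can give). Genes 50 apart correlated at 0.0296 in Hec1a (p = 0.00200) and at 0.0075 in Ishikawa (p = 0.225). Differences between 2 arrays of 1 group hold no contrast of the vectors, and they correlated at up to 0.0448 in Hec1a and 0.0532 in Ishikawa for adjacent genes, and at up to 0.0318 and 0.0167 for genes 50 apart. Such correlations therefore arise between arrays of the same cells and vector too, and copy number cannot be told apart from shared regulation of neighbours, from differences between single arrays or from probe composition, which was not tested. Other splits of the 6 arrays, which gave up to 0.0562 in Hec1a and 0.0540 in Ishikawa, still hold part of the contrast of the vectors and so do not decide this.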
